A study of Mus musculus with 6 samples.

How the data were processed

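RNA sequencing of wild-type C57BL6/J mouse retina was analysed. Per the titles in the labels, the 6 samples are 3 biological replicates with 2 technical replicates each, and each library came from a pool of 5 mice. Both technical replicates of a biological replicate point to 1 deposited table, so each biological replicate had 1 column of values and n was 3. The source labels of the samples number them differently and pair them across the titles' replicates. The titles, which go with the file each sample names, were followed. If the source labels were right instead, each column would combine material of 2 sources and the 3 columns would not be independent, so the SDs and p-values rest on the titles. The series design also speaks of ocular tissue of other genotypes, which was not analysed here. With 1 group there was no comparison between groups, and the retina was described with its spread between pools.

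The deposited values were taken as RPKM, which is inferred from the values because no header or label names the unit. They were decimals with 2 places, and their product with transcript length in kb summed to 788112, 830946 and 731224 in replicates 1, 2 and 3, as RPKM allows (the bound is the scale of RPKM, 1000000). RPKM and FPKM could not be told apart. Per the submitters' processing notes, the genome build was mm9 and the tools were GSNAP and HTSeq, with no version given. The annotation and the filters behind the rows are not given in the sources used here. Each table held 15468 rows in 1 order. 3 symbols stood on 2 rows with identical values and were kept once, which left 15465 genes. No coordinates are printed, because the annotation used here (GENCODE M21, RefSeq GRCm38.p6) is of another build and served only for symbols and transcript lengths. A length, the median over transcripts linked to RefSeq, was found for 15249 genes (98.6%).

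The sequencing depth is unknown. Low values were searched for steps of whole reads with transcript length as the scale, and the fit was no closer than with shuffled lengths in a way that could be relied on (16, 39 and 163 of 200 shuffles were as close in replicates 1, 2 and 3). No interval or detection floor that needs a depth is therefore given. A value of 0 is reported only as listed at 0, since 149 genes, among them the ribosomal gene Rpl26, were at 0 in all 3 replicates.

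The tests fixed before the data were examined assumed counts, and the unit did not allow them. They were replaced by tests on log2(RPKM + 0.1) for the 12562 genes with a mean of 1 RPKM or more, after division by a trimmed mean of log ratios (30% of log ratios and 5% of means trimmed from each end). Folds are on this scale, which understates differences of low genes. The scaling factors were 0.984, 1.09 and 0.934, and without them the replicates stood apart by -0.02, 0.12 and -0.10 on the log2 scale. Levels are printed as deposited, with the SD over replicates for most list medians and for part of the genes. A gene mean printed without an SD says nothing of its spread. The chi-square test of rod and cone counts was not run. Detection was set at 1 RPKM in every replicate. The median SD over replicates on the log2 scale took the place of the coefficient of variation.

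Genes varying between replicates were tested with limma 3.58.1 (R 4.3.3, statmod 1.5.0) by setting each gene's variance against the prior variance at its mean in an F test, with Benjamini-Hochberg adjustment at 0.05. The version chosen first, once the unit was known, used limma's non-robust trended prior on all genes. It called 0 genes, and on simulated values for 12562 genes it recovered 0% of 200 planted changes of 1, 2 or 3 on the log2 scale. The robust trended prior recovered 1.49% of changes of 1, 85.1% of changes of 2 and 100% of changes of 3, with 1 call among unchanged genes. With 600 rows displaced as well, in replicate 2 only, it recovered 0%, 37.3% and 98.5%. The simulated spread did not match the deposited values. There the non-robust trended prior called 45 genes once the genes described next were left out. The simulation is therefore a limited guide to the choice of prior. The robust prior was made the main test on the basis of this simulation. That decision was taken after the counts of both on the deposited values had been seen, among 6 versions run (3 settings of the prior, each with all genes and without the genes described next). All 6 counts are given in the closing section.

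Many values stood on rows where replicates differed by several powers of 10. These rows had symbols that equal another symbol followed by a digit, such as Tppp and Tppp2, or were such a shorter symbol. Symbols of this kind among those of the files and RefSeq, called digit-extended symbols here, numbered 2726, of which 2145 passed the mean filter. This definition, and the repeat of each test without these genes (10417 genes), were chosen after the data were seen. A narrower definition from the files' symbols alone was also tried.

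Before the data were examined, 33 gene lists (17 cell-type and 16 functional), 10 pairs of rod and cone counterparts and 17 gene families were fixed. A list's level was the median of its members' mean log2 value against 10000 random lists of the same size (permutation, two-sided). Its shift was the range over replicates of the members' median deviation against 10000 lists matched on mean in 10 bins (permutation, one-sided). Both were adjusted over the 31 lists with 3 or more members past the filter. Both tests used only the members past the filter, whereas the printed RPKM medians cover all members among the rows. On simulated lists of 15 genes among 12562, a planted shift of 0.5 was called (adjusted p = 0.0102) and 0 of 100 unchanged lists were. Simulated genes varied independently and the unchanged lists were drawn at random. The simulation therefore does not show how often lists of genes that vary together are called. Genes are not independent replicates, and these p-values describe these libraries. A sign-flip test over 3 replicates cannot give a two-sided p under 0.25, so ratios of rod to cone genes carry no test.

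The genes named were, by a rule fixed before the data were examined, the 10 of highest mean, all members of the pairs, up to 3 members of highest mean per list, all of the Y-linked and Xist list, the first and second member per family, and for variation the 12 of smallest p plus up to 15 called list members. Some items the rule covers are not reported here. The rule was applied to all genes and again without digit-extended symbols. Alternatives were other scalings, pseudocounts (0.01 and 1), filters, the mean of members, each replicate left out, removal of a trend on transcript length (median deviation in 50 length bins), and the other priors. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.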

Results

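The transcriptome of the wild-type mouse retina was measured by RNA sequencing in 3 biological replicates, each a pool of retinas from 5 C57BL6/J mice with its 2 technical replicates in 1 column of RPKM values. This grouping follows the sample titles, with which the source labels conflict, and the SDs rest on it. The values summed to 275995, 302634 and 249532 RPKM in replicates 1, 2 and 3, and the read depth behind them is unknown. A total of 11978 of 15465 genes had 1 RPKM or more in every replicate. Means of 10 RPKM or more were reached by 5851 genes, of 100 or more by 326 and of 1000 or more by 12. The median SD between replicates was 0.15 on the log2 scale, a factor of 1.11.

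Rod photoreceptor transcripts headed the retina. Gnat1, the rod transducin alpha subunit, had 5103 ± 332 RPKM (SD, n = 3), and Pde6g, the inhibitory subunit of the rod phosphodiesterase, had 2330 ± 503 RPKM. Also among the 10 genes of highest mean were Unc119 (1820 ± 310 RPKM), a carrier of lipid-modified transducin, the disc rim genes Rom1 (1675 ± 314) and Prph2 (1531 ± 110), Sag (1400 ± 221), the rod arrestin, and Rcvrn (1288 ± 270), a calcium sensor. The lens proteins Cryaa (1674 ± 344 RPKM) and Crybb2 (1497 ± 252) were also among them. The 10 genes of highest mean held 10.7% ± 0.179 of the summed RPKM and the first 100 held 24.3% ± 0.295. Prph2 has a digit-extended symbol, and its row is less certain than the others.

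The retina holds both rods and cones, and several of their transduction proteins come from separate genes. In each of 10 pairs the rod gene exceeded its cone counterpart in 3 of 3 replicates. The median over pairs was 5.11 ± 0.16 on the log2 scale (SD, n = 3), a factor of 34.6. Gnat1 exceeded Gnat2 54.4-fold, Pde6a with Pde6b exceeded Pde6c 42-fold, and Pde6g exceeded Pde6h 31.1-fold. The channel subunits behaved alike, with Cnga1 over Cnga3 at 40.5-fold and Cngb1 over Cngb3 at 29.2-fold, and the exchanger Slc24a1 exceeded Slc24a2 44.6-fold. Sag exceeded Arr3, the cone arrestin, 13.3-fold. The transducin beta and gamma genes differed least, with Gnb1 over Gnb3 at 3.64-fold and Gngt1 over Gngt2 at 2.99-fold. All are ratios in whole retina, where expression of either gene in other cell types was not separated. The SD of the ratios of the 10 pairs was between 0.07 and 0.30 on the log2 scale. An exact sign-flip test over 3 replicates cannot give a p under 0.25. Among the cone pigments, Opn1sw stood at 2.09 ± 0.103 times Opn1mw. RPKM divides by a transcript length, and multiplying it back moved 7 of the 10 ratios by more than their SD, with that of Pde6g to Pde6h going from 4.96 to 2.24 on the log2 scale. A pseudocount of 1 moved 3 of the 10, and the rod gene stayed higher in each case.

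**Figure D1:**
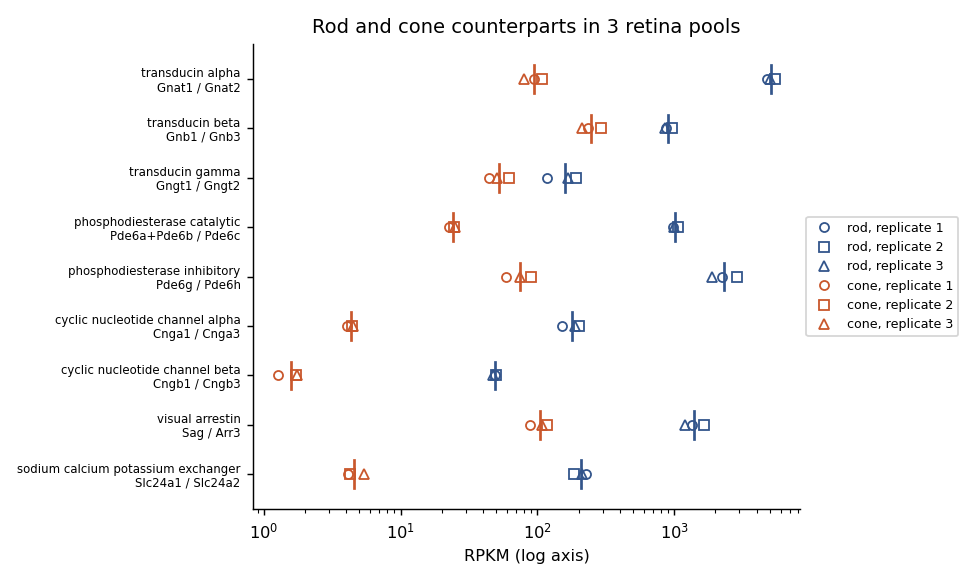
RPKM (log axis) of rod genes (blue) and cone genes (orange) of 9 protein pairs, with a symbol per replicate and a bar at the mean of 3 replicates. The rod gene lies to the right in every pair, by 54.4-fold for transducin alpha and 2.99-fold for transducin gamma.

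Lists of cell-type markers followed the same order. The 14 rod genes had a median of 496 ± 42.8 RPKM (SD, n = 3), the 11 Muller glia genes 61.1 ± 12.1, the 13 cone genes 52.4 ± 9.03 and the 16 bipolar cell genes 26.5 ± 1.21. These 4 lists stood above random lists of expressed genes (permutation test, adjusted p = 0.000689 for rods and cones, 0.00113 for Muller glia and 0.0062 for bipolar cells). The leading Muller glia genes were Apoe (756 ± 209 RPKM), Clu (375 ± 88.2) and Glul (329 ± 71.9), the glutamine synthetase. The bipolar cell list included Gng13 (51.9 ± 5.25) and Grm6 (47.3 ± 5.31), the receptor of ON bipolar cells. The cone list was led by Gnb3 (247 ± 42.1), Opn1sw (187 ± 9.99) and Arr3 (105 ± 15.2). Ganglion cell genes had a median of 14.9 ± 1.88 RPKM, with Nefl (128 ± 6.92), Thy1 (110 ± 14.2) and Sncg (86.2 ± 13.4) first. Amacrine cell genes had a median of 6.5 ± 0.715, with Slc6a9 (80.8 ± 8.27), Gad1 (66 ± 9.26) and Slc32a1 (54.9 ± 7.21) first. Neither list was apart from random lists (adjusted p = 0.223 and 0.566, permutation test).

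Medians of further cell-type lists were also taken. They were 6.25 ± 1.19 RPKM for astrocytes (S100b 6.55, Gfap 6.25, Pdgfra 1.7), 6.05 ± 0.117 for vascular cells (Kdr 18.9, Cldn5 17.1, Acta2 16.1), 2.44 ± 0.185 for microglia (C1qb 7.24, Ctss 6.13) and 2.13 ± 0.0458 for horizontal cells (Calb1 12.8, Lhx1 2.13, Onecut1 1.76). The myelin list had a median of 0.193 ± 0.00764 RPKM, with Cnp at 10.5 and Mbp at 5.43. The red blood cell list had too few members past the filter for a test. Only 4 of its 8 members were among the rows, without any of its beta-globin genes, and these had a median of 0.133 RPKM. That median is therefore no measure of blood content. Of its genes, Hba-a1 and Hba-a2 were listed at 0, Alas2 had 0.487 RPKM and Slc4a1, with a digit-extended symbol, 1.42. Lists of markers of tissues next to the retina, whose source in these samples was not tested, had medians of 10.7 ± 4 RPKM for pigment epithelium genes (Ttr 131, Dct 99.5, Rgr 90.2), 15.5 ± 8.16 for non-crystallin lens genes (Mip 39, Lim2 36.4, Lenep 30.1) and 230 ± 83.8 for crystallins, among them Cryba1 (576 ± 17.7). Crystallins stood above random lists (adjusted p = 0.000689). Cornea and conjunctiva genes had a median of 1.23 ± 0.1 (Dcn 7.23, Krt5 4.48, Aldh3a1 4.47) and skeletal muscle genes 1.0 ± 1.08 (Myl1 10.5, with a digit-extended symbol, Mylpf 4.58, Acta1 3.2). The mean of Myl1 rests on replicate 3, with 0.34, 2.26 and 28.9 RPKM in replicates 1, 2 and 3. The cell-type lists tested that were not apart from random lists had adjusted p between 0.0635 and 0.774 (permutation test). Only members past the filter were tested, 3 of 8 for myelin, 6 of 10 for muscle and 6 of 9 for cornea. Leaving out low members works against a low call, so these p-values do not apply to the medians over all members.

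**Figure D2:**
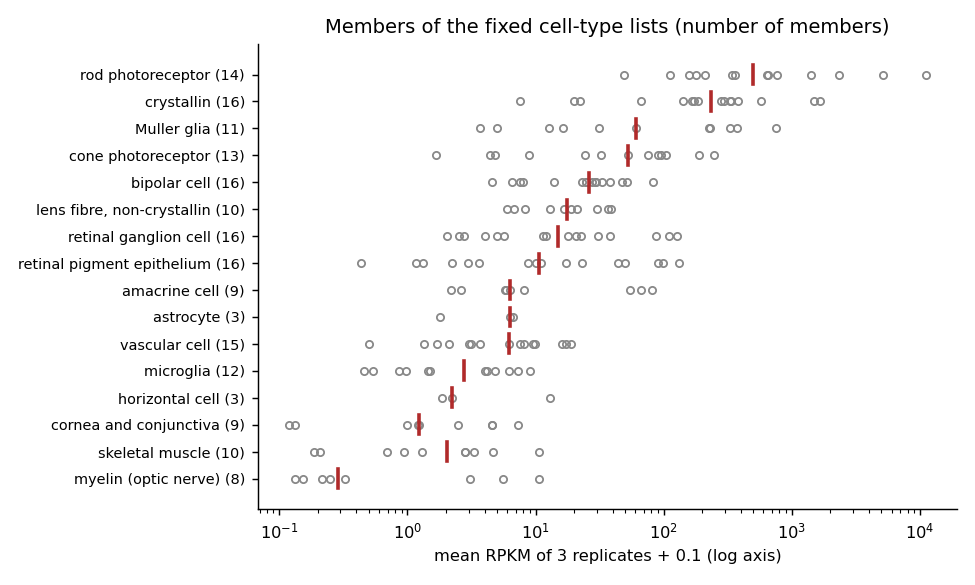
Mean RPKM of 3 replicates plus 0.1 (log axis) of each member of the fixed cell-type lists (circles), with the median of members (red bar) and the number of members in brackets. Among the lists drawn, rod genes have the highest median, 496 RPKM, and myelin genes the lowest, 0.193 RPKM.

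Functional lists of photoreceptor genes were high. Median values were 213 ± 13.1 RPKM for 25 outer segment genes, 94.7 ± 6.65 for photoreceptor transcription factors (Nrl 767, Nr2e3 342, Crx 304), 75.4 ± 2.81 for ribbon synapse genes (Slc17a7 696, Syp 314, Cplx4 222), 59.8 ± 4.94 for inherited retinal disease genes and 26.6 ± 2.73 for visual cycle genes (Rbp3 777, Rlbp1 225, Abca4 140). Energy metabolism was also high, with 96.1 ± 12.7 RPKM for glycolysis (Aldoa 1099, Pkm2 855 with a digit-extended symbol, Ldha 501) and 67.4 ± 12.6 for oxidative phosphorylation (Atp5b 559, Atp5a1 293, Cox8a 256). Cytosolic ribosome genes had 20 ± 4.19, led by Rpl8 (310), Rplp1 (208) and Rps3 (140), and their levels are uncertain where near-identical copies share reads. All 8 passed the permutation test, with adjusted p between 0.000689 and 0.00811. Together with 5 cell-type lists, 13 of 31 lists were high and 0 were low. The count of 0 low depends on the filter, since members with a mean under 1 RPKM were left out of this test. With no filter 15 lists passed as high and 4 as low, and by the mean of members 14 and 5. Without digit-extended symbols the interferon response list passed as low (adjusted p = 0.0412, permutation test), and without replicate 3 the cornea and conjunctiva, skeletal muscle and proliferation lists did. Without replicate 2 the circadian clock list passed as high.

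The other 7 functional lists tested did not pass (permutation test, adjusted p between 0.0527 and 0.345). The test used only members past the filter, among them 9 of 20 for proliferation, 11 of 19 for interferon response and 11 of 17 for gliosis and injury. The medians that follow cover all members among the rows, so these p-values do not apply to them where members were left out. Medians of these 7 lists were 18.7 ± 0.278 RPKM for the circadian clock (Nr1d1 117, Dbp 59.8, Tef 59.1), 13.1 ± 2.13 for heat shock (Hsp90ab1 171, Hspa5 68.5, Hsp90aa1 49.2), 12.7 ± 0.617 for cilium transport (Rpgrip1 135, Ift20 46.7, Bbs4 42.4) and 10 ± 1.31 for immediate early genes (Jund 46.3, Btg2 31.2, Dusp1 24.8). Gliosis and injury genes had a median of 1.92 ± 0.316 (Stat3 15, Cp 13.4, Serpina3n 7.13), interferon response genes 1.27 ± 0.34 (Usp18 54.7, Irf7 13.8, Stat2 9.87) and proliferation genes 0.695 ± 0.14 (Cdk1 12.4, Pcna 10.2, Ccna2 7.23). Dusp1, Usp18 and Cdk1 have digit-extended symbols. In replicates 1, 2 and 3, Dusp1 had 11.5, 9.21 and 53.6 RPKM and Usp18 had 162, 1.06 and 0.81, so their means rest largely on 1 replicate. The list of Y-linked genes and Xist had too few members past the filter for a test. Xist had 34.4, 42.4 and 63.4 RPKM in replicates 1, 2 and 3, and Ddx3y and Kdm5d were listed at 0 in each.

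Within gene families 1 member often took most of the RPKM. Slc17a7 took 98% ± 0.235 of the vesicular glutamate transporters, ahead of Slc17a6 with 1.59%. In energy metabolism, Ckb (90.8%) preceded Ckmt1 (8.81%), Eno2 (90.5%) preceded Eno3 (9.38%), Aldoa (83.8%) preceded Aldoc (16.2%), Ldha (83.5%) preceded Ldhb (16.5%), Hk1 (72.7%) preceded Hk2 (26.2%), and Pfkl (49.6%) preceded Pfkp (33.8%). Among transporters and pumps, Atp1b2 (66.2%) preceded Atp1b1 (27.8%), Slc2a3 (79.9%) preceded Slc2a1 (17.4%), Slc16a3 (58.3%) preceded Slc16a8 (36.3%), and Slc1a7 (48.5%) preceded Slc1a3 (25.4%). Among signalling and synaptic genes, Gucy2e (85.9%) preceded Gucy2f (14.1%), Guca1a (53.7%) preceded Guca1b (46.3%), and Cplx4 (46.5%) preceded Cplx3 (31.4%). SDs of these shares over 3 replicates were at most 4.45 percentage points. Slc2a1 and Slc16a1, the latter with 3.36% of the monocarboxylate transporters that Slc16a3 led, have digit-extended symbols. The shares in these families are less certain for that reason. Eno1, the third enolase, had 0.263 RPKM (0.111% of the family). The enolase shares are uncertain where genes share reads with near-identical copies, and that of Eno2 depends on whether this low Eno1 value is right.

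The replicates were then compared with each other. With limma's robust prior, 687 of 12562 genes varied more than genes of their abundance (adjusted p under 0.05), of which 638 (92.9%) had digit-extended symbols. The count was 467, 302 and 456 without replicate 1, 2 and 3, for the genes varying between replicates in the remaining pair. The 12 of smallest p were Tspan32, Stk3, Slc6a15, Tppp, Gm6084, Abhd12b, Gpr151, Hp, Ttc32, Slc38a11, Rbm33 and Tmem92-ps, all with such symbols. Stk3 had 491, 0.25 and 491 RPKM in replicates 1, 2 and 3, and Slc6a15 had 172, 150 and 0.05. Of the called genes, 32 were in a fixed list. Among the 15 of these with the smallest p, those with digit-extended symbols were Usp18 (162, 1.06 and 0.81 RPKM), Cox7b (23.8, 0.04 and 0.05), Dnajb1, Myl1, A2m, Myh13, Slc4a1 and Dusp1. Across genes, correlations of log2 values between replicates lay between 0.377 and 0.688 for digit-extended symbols and between 0.983 and 0.989 for other symbols. The non-robust prior that had been chosen first called 0 of the 12562 genes, with 705 at an unadjusted p under 0.05.

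**Figure D3:**
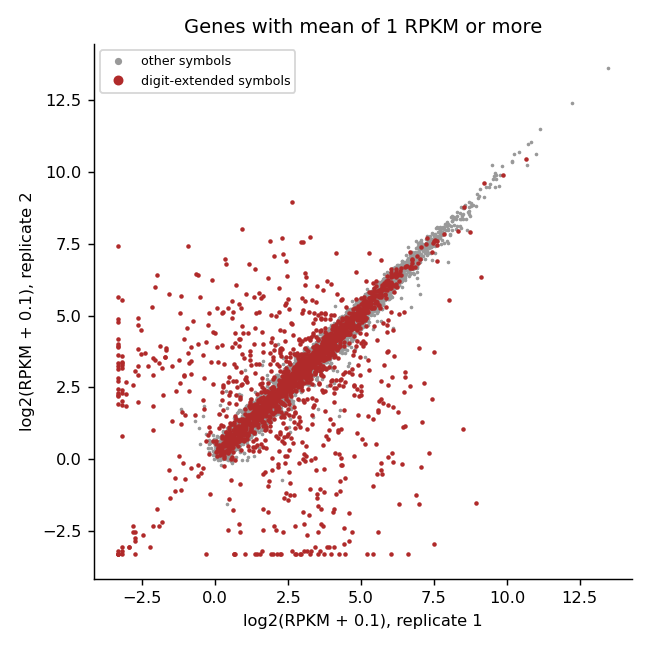
log2(RPKM + 0.1) in replicate 2 against replicate 1 for the 12562 genes with a mean of 1 RPKM or more. Digit-extended symbols (red) spread far from the diagonal, with a Pearson r across genes of 0.477 against 0.989 for other symbols (grey).

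Without digit-extended symbols, a repeat chosen after the data were seen, the same test called 92 of 10417 genes (49 of them also with all genes). The 12 genes of smallest p included 5 gamma-crystallins of the lens. In replicates 1, 2 and 3, Cryge had 35.2, 11.7 and 154 RPKM, Crygf 11.3, 3.26 and 44.8, Crygb 105, 38.8 and 354, Cryga 16.6, 6.14 and 43.8, Crygd 130, 54 and 371, and Crygc 250, 115 and 635. The lens genes Lgsn (10.2, 2.66 and 43), which had the smallest p, and Bfsp1 (14.1, 5.78 and 29.8) had the same order of replicates. The muscle genes Tnni2 (0.34, 3.21 and 0.04) and Acta1 (1.93, 6.58 and 1.08) and the keratin Krt5 (1.95, 8.41 and 3.08) were highest in replicate 2. The pigment genes Pmel (62.7, 51.7 and 18.3) and Mlana (23.7, 20.6 and 7.09) were lowest in replicate 3, as were Dcn (10.7, 9.0 and 1.97) and Acta2 (21.3, 20.8 and 6.3). Scarna9 (4.76, 0.5 and 0.34), Scarna2 (19, 2.73 and 7.88) and Rmrp (19.3, 3.18 and 9.1), all non-coding RNAs, were highest in replicate 1, and Birc7 (1.21, 0.24 and 3.89) in replicate 3. Adjusted over the list alone, 7 of 16 crystallins, 7 of 10 other lens genes, 6 pigment epithelium genes, 4 muscle genes and 3 cornea genes varied, against 6, 6, 5, 3 and 2 over all 10417 genes. Of the other called lens genes, Lim2 (33.1, 23.93 and 52.28 RPKM), Lenep (23.49, 19.72 and 46.94) and Bfsp2 (11.98, 8.96 and 17.65) had the order above. Foxe3 (8.54, 7.96 and 3.7 RPKM) did not, and was lowest in replicate 3. The number called was 45 with the non-robust prior and 34 after a trend on transcript length was removed, and between 41 and 47 with a replicate left out.

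Medians of some lists also differed between pools. In the shift test 8 of 31 lists passed (permutation test, adjusted p between 0.00062 and 0.0229). Skeletal muscle genes spanned 1.29 on the log2 scale between replicates, non-crystallin lens genes 0.81, cornea and conjunctiva genes 0.70, pigment epithelium genes 0.61 and crystallins 0.53. The muscle and cornea spans rest on 6 members each past the filter, some with digit-extended symbols, and within the lens lists only part of the members varied, as given above. Without digit-extended symbols the same 8 lists passed. The span was then 1.70 for muscle and 0.73 for cornea, on 4 members each. Smaller spans were found for the cytosolic ribosome (0.30), oxidative phosphorylation (0.29) and cilium transport (0.17). Rod genes spanned 0.04 (adjusted p = 0.982) and cone genes 0.13 (adjusted p = 0.603), less than or near the median of random lists. By the mean of members, 1 of 31 lists passed, and without replicate 2 only 3 did. After the length trend was removed, the ribosome (adjusted p = 0.192, permutation) and oxidative phosphorylation (adjusted p = 0.49) no longer passed.

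**Figure D4:**
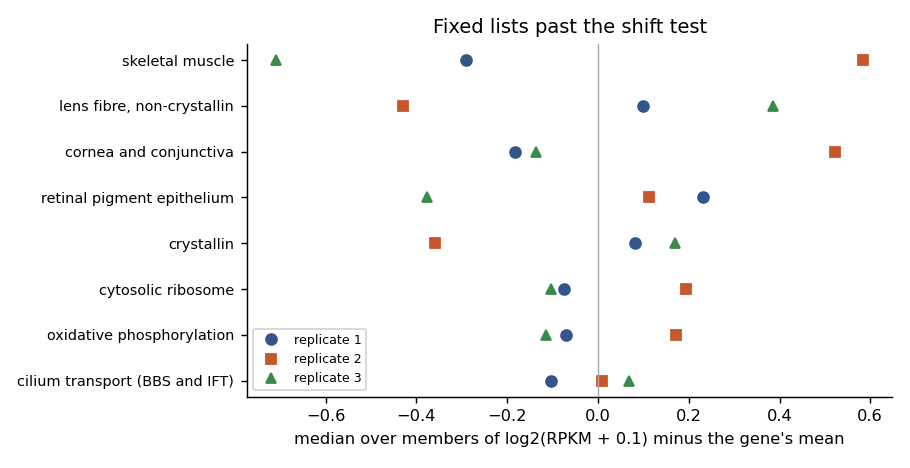
Median over members of scaled log2(RPKM + 0.1) minus the gene's mean, for each replicate and each of the 8 lists past the shift test. Skeletal muscle genes span 1.29 and cilium transport genes 0.17.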

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

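Leaving out replicates, the mean of members, no filter and the smaller set of rod to cone pairs were planned. All other alternatives, the removal of a length trend among them, were chosen after seeing the data. The 6 versions of the variance test gave 687 (robust), 0 (non-robust trended, chosen first, with 705 genes at an unadjusted p under 0.05) and 0 (non-robust single prior, with 710) for all genes. Without digit-extended symbols they gave 92, 45 and 42. Genes called by the last 2 were all among the 92. The narrower definition gave 119, and removal of the length trend 34. With a replicate left out, the genes varying between replicates numbered from 302 (without replicate 2) to 467, with 456 without replicate 3. The cause of these moves was not tested. Both non-robust priors recovered 0% of simulated changes among 12562 genes. That does not match their 45 and 42 calls without digit-extended symbols, so the simulation does not account for those counts. The number of shifted lists was 1 by the mean of members and from 3 (without replicate 2) to 7 with a replicate left out. With a filter at 0.1 RPKM 20 lists passed the level test, 15 as high and 5 as low. Multiplying by transcript length gave a median rod to cone ratio of 4.57 on the log2 scale (5.11 before) and a median leading family share of 77.7% (79.9% before). Without digit-extended symbols that share was 83.5%, because members left the families, and the first 100 genes held 26.6%, because fewer genes made up the total. Results on detected genes and the median SD moved by less than 1.5 times under the alternatives run. Of 403 list levels under alternatives, 373 kept their side of the threshold and 30 came to pass it, 8 as high and 22 as low. Of 403 list shifts, 382 kept it, 19 lost it and 2 gained it. Of 553 results on the variation of a named gene, 114 lost their call, 39 of 39 genes with each non-robust prior on all genes, 5 of 37 after removal of the length trend, 2 of 39 with a pseudocount of 0.01, and 7 of 34, 10 of 38 and 12 of 37 without replicate 1, 2 and 3. By the mean of members 7 lists lost their shift. Crystallins lost it without replicate 2 and without scaling, cornea without replicate 2 or 3, muscle, ribosome and oxidative phosphorylation without replicate 2, cilium transport without replicate 1 or 3 and without scaling, and ribosome and oxidative phosphorylation after removal of the length trend. None of the results listed reversed. Count-based alternatives (10 counts, Poisson, negative binomial dispersions) were not run because the files hold RPKM, nor was the one without mitochondrial genes, since none is among the rows. Depth is unknown and limits low values.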

Other observations

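The tests of the displaced rows and of the lens genes were chosen after the results were seen, except the comparison of exchanged rows. For that comparison and for the length test, the outcome each explanation predicts was written down before the test was run, although the patterns themselves had been seen. Among genes with other symbols, the histone genes Hist2h4 (5.86, 1.82 and 4.35 RPKM in replicates 1, 2 and 3) and Hist1h4d (5.72, 2.07 and 4.4) and Scarna17 (67.9, 23.7 and 48.6) were lowest in replicate 2, as were Scarna2 and Rmrp. Asprv1 (4.31, 15.9 and 3.99), Lypd2 (3, 10.7 and 2.33), Psca (2.93, 9.59 and 2.33) and Krt6b (0.67, 3.47 and 0.74), none in a fixed list, were highest in that replicate. These genes were picked after their values were seen.

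Rows with 1 replicate more than 8-fold from the median numbered 367, and 99.7% of them had digit-extended symbols, against 17.1% of kept genes. A candidate explanation is that values were displaced among rows whose symbols extend one another by digits, as a sort of symbol and value in 1 string would do. In 358 pairs of nearby rows with opposite changes, the product of value and length differed by a median of 0.818 on the log2 scale, against 1.91 when pairs were permuted (permutation p = 0.0001, the smallest 10000 permutations can give). A row could enter more than 1 comparison of replicates and more than 1 pair. The pairs are therefore not independent, and the p-value does not allow for that and overstates the evidence. Noise of low values near the detection limit is argued against as the source of these rows, since their median level was 0.886 times that of all kept genes. That level is a mean over replicates, which 1 high value can carry, so other values of a row can still lie near the limit. The step of displacement stays open, since values alone differed by 0.944, rows displaced alike in all replicates would escape this comparison, and no biological explanation was tested.

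Lens genes stood apart between pools, with the 6 gamma-crystallins Cryga to Crygf higher in replicate 3 than 2 by a median of 3.22 on the log2 scale. Displaced rows are argued against, since 0% of the 26 members of both lens lists have digit-extended symbols, and so are reads shared among Cryga to Crygf, since the sum of these 6 differed by 3.03. Lens material in different amounts may contribute. The 20 other members, Crygs (0.68) and Crygn (-0.91) among them, however differed by a median of 0.288, up to 4.18 for Lgsn. Bfsp1 (2.56), Lenep (1.47), Lim2 (1.34) and Bfsp2 (1.19) were also higher in replicate 3 than 2, and 4 of the 20 were lower. Retinal expression of the 20 other members could hide a rise, so lens carry-over cannot be told apart from other sources. The age of the mice and the dissection are not given in the labels used here and were not tested.

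The ribosome and oxidative phosphorylation lists were highest in replicate 2. A candidate explanation is a trend on transcript length between libraries, because across 12407 genes the deviation from the gene's mean had a Spearman rho with length of -0.555 in replicate 2 and 0.435 in replicate 3. After its removal the spans fell from 0.30 to 0.11 for the ribosome (permutation p = 0.0512) and from 0.29 to 0.10 for oxidative phosphorylation (permutation p = 0.277). The ribosome value lies near the threshold, and a smaller difference beyond length stays open. Cilium transport kept its call, with a span of 0.21. Genes are not independent replicates, and no biological explanation was tested.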
